A study of Homo sapiens with 6 samples.

How the data were processed

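Poly(A)-selected RNA of T47D, an oestrogen receptor-positive line derived from a human breast ductal carcinoma, was sequenced in 6 libraries after random-primed cDNA synthesis, adaptor ligation and circularisation of the library, per the labels' protocols. The cells carried lentiviral short hairpin RNA, either non-targeting (shNC, 3 libraries) or against CUEDC1 (shCUEDC1, 3 libraries). The labels do not state how many hairpins were used, so an off-target effect of a hairpin cannot be told from the loss of CUEDC1. The series describes the 3 libraries of a group as biological replicates. No label says whether they came from separate infections or from 1 stable line grown in parallel, so the p-values measure the spread between these libraries. The genome build was GRCh38 with patch p13, per the submitters' processing notes. The aligner, the counting program and its use of strand are not given in the sources used here.

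The authors deposited 1 table of 17758 genes with Entrez identifiers and unique symbols. Its estimated counts, per the file headers read counts, are not normalised and are fractional: between 21.8% and 24.7% of a library's values are whole. The deposited FPKM values are scaled by the authors to gene length and library size. The deposited TPM values are a constant multiple of FPKM within a library, between 2.01 and 2.10. A further signal column per library holds the counts divided by 1 size factor per library, computed by the authors. The authors' group means were not used. The table holds no messenger RNAs of the mitochondrial genome, so that list is not analysed here, and it carries no pathway annotation, so the planned pathway enrichment was not made.

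The estimated counts were rounded to whole numbers, filtered with filterByExpr (minimum count 10) and normalised by TMM. The groups were compared with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p below 0.05 are called changed, and those that also differ by more than 2-fold are counted separately, which is the criterion the series states for its own DESeq2 list. Levels are TMM-normalised CPM, counts scaled to a common library size, given as mean ± SD of 3 libraries, and fold changes are shCUEDC1 over shNC on the log2 scale with a standard error (SE) or a 95% interval. CUEDC1, CACNG4 and SLC2A1 were also compared by an exact two-sided permutation test of 3 against 3 libraries, for which 0.1 is the smallest possible p.

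Gene lists were fixed before the data were examined, 22 in all: calcium channel subunits, glycolysis, PI3K AKT core, FOXO targets, oestrogen response, luminal identity, basal and mesenchymal markers, stromal and immune markers, cell cycle G2 M, cell cycle G1 S, interferon response, ATF4 and unfolded protein response, hypoxia response, cholesterol synthesis, fatty acid synthesis, mitochondrially encoded, respiratory chain nuclear, TGF beta targets, p53 targets, immediate early genes, replication-dependent histones and ribosomal proteins. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists with tested members. The named genes also follow a rule set beforehand. They are CUEDC1 and the genes the series names, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean FPKM is at least 1 in the higher group, and up to 4 called members of each list with the smallest p. Where a list had no called member, its members with the highest level were to be named. A few genes that the rule takes are not reported here, and they were not replaced.

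Alternatives fixed beforehand were RLE size factors, no filter beyond 1 count in all, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 0.5), the replicate number as a block, and each library left out in turn. For the lists they also included an estimated correlation, ranks and fry. Offsets for GC content and transcript length were added after seeing the data, with both taken from GENCODE v29 on GRCh38, which gave values for 99.2% of tested genes.

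The total per library was between 18924327 and 19731609 estimated reads. On simulated counts with the means, dispersions and library sizes of shCUEDC1 against shNC, 13702 genes were tested with edgeR, which recovered 70% of 100 genes changed 1.5-fold and 85% of 100 genes changed 2-fold. Of its 171 calls there, 9.36% were unchanged genes, above the nominal rate.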

Results

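RNA levels were measured in 6 libraries of T47D cells, 3 with a non-targeting short hairpin RNA (shNC) and 3 with short hairpin RNA against CUEDC1 (shCUEDC1). Totals ranged from 18924327 estimated reads in shNC 3 to 19731609 in shNC 2, and 13824 genes were tested. The first principal component, with 42.7% of the variance, separated the groups. The second, with 26.0%, set shNC 3 apart from the other libraries. The SD of the log2 difference over genes with a mean of at least 10 CPM was 0.107 between shNC 1 and shNC 2. It was between 0.117 and 0.124 for pairs of shCUEDC1 libraries. It was 0.236 between shNC 1 and shNC 3 and 0.256 between shNC 2 and shNC 3, against 0.231 to 0.239 between shNC 1 or 2 and the shCUEDC1 libraries and 0.261 to 0.272 between shNC 3 and those. So shNC 3 differed from its own group about as much as shNC 1 and 2 differed from the knockdown.

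CUEDC1 (Entrez 404093), which encodes a protein with a ubiquitin-binding CUE domain, was the target of the short hairpin RNA and fell in every shCUEDC1 library. It lies on chromosome 17 from 57861243 to 57955323 on the minus strand (GRCh38). Its level was 110, 109 and 93.3 CPM in shNC 1, 2 and 3, and 31.4, 33.8 and 32.0 CPM in shCUEDC1 1, 2 and 3. CUEDC1 fell by 68.9% (95% interval -72.3% to -65.0%), a log2 change of -1.68 (SE 0.0755, edgeR quasi-likelihood adjusted p = 9.27e-06). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The series states a reduction of more than 70% for CUEDC1 mRNA by another method. The estimate here is smaller, and its interval includes 70% but not reductions above 72.3%.

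CACNG4 (Entrez 27092), an auxiliary gamma subunit of voltage-gated calcium channels, is the gene that the series names as downstream of CUEDC1. It lies on chromosome 17 from 66964910 to 67033398 on the plus strand. CACNG4 fell from 150 ± 7.73 CPM in shNC to 104 ± 1.16 CPM in shCUEDC1 (SD, n = 3 each). Its log2 change was -0.53 (95% interval -0.65 to -0.42, edgeR adjusted p = 3.86e-04), and the exact permutation p was 0.1. The interval leaves out a 2-fold fall, so CACNG4 was called changed but was not among the genes that pass the fold criterion of the series. The study chose CACNG4 on these samples, so its fall here is not independent evidence.

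The series also names 3 genes of glucose metabolism. SLC2A1 (Entrez 6513), the glucose transporter GLUT1, was at 74.0 ± 3.62 CPM in shNC and 73.9 ± 2.13 CPM in shCUEDC1 (SD, n = 3 each). Its log2 difference was -0.003 (95% interval -0.13 to 0.12, edgeR adjusted p = 0.98), with an exact permutation p of 1. LDHA, lactate dehydrogenase A, differed by 0.04 on the log2 scale (95% interval -0.24 to 0.32, edgeR adjusted p = 0.875). HK2, hexokinase 2, differed by 0.22 (SE 0.0627, edgeR adjusted p = 0.0574) and was higher in all 3 shCUEDC1 libraries than in any shNC library. Without shNC 3, HK2 differed by 0.27 (edgeR adjusted p = 3.36e-04). With all libraries and offsets for GC content and length, HK2 differed by 0.24 (edgeR adjusted p = 0.0211). No other fit called HK2. Its edgeR adjusted p was 0.122 to 0.201 when any other single library was left out, and by limma-trend on FPKM it was 0.108. LDHA differed by -0.09 without shNC 3, with an edgeR adjusted p of 0.164.

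**Figure D1:**
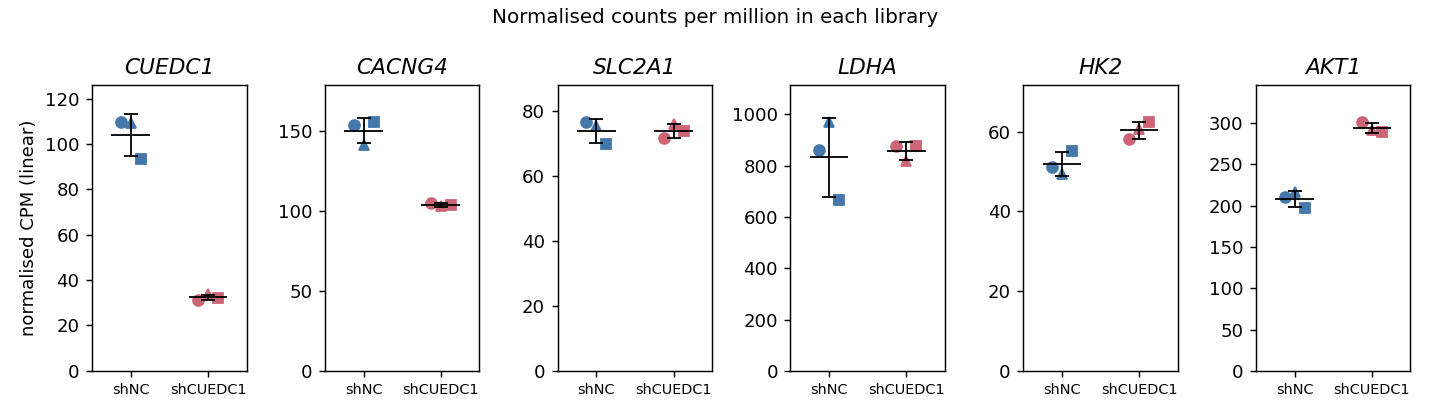
Normalised CPM (linear axis from 0) of CUEDC1, CACNG4, SLC2A1, LDHA, HK2 and AKT1 in 3 shNC and 3 shCUEDC1 libraries, with circles, triangles and squares for replicates 1, 2 and 3 and black lines for the mean and SD. CUEDC1 averaged 104 CPM in shNC and 32.4 CPM in shCUEDC1, and SLC2A1 averaged 74.0 and 73.9 CPM.

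Over all genes, 1377 of the 13824 tested differed between the groups, 717 higher and 660 lower in shCUEDC1 (edgeR, Benjamini-Hochberg adjusted p below 0.05). Changes were mostly small, with 962 of the called genes under 1.5-fold. More than 2-fold change was found for 162 genes, 56 higher and 106 lower. The series states 154 genes by DESeq2, 50 higher and 104 lower, and DESeq2 here gave 149, with 56 higher and 93 lower. The groups did not overlap for 31.3% of the genes tested, where chance gives 10% for 3 against 3 libraries. The count of changed genes moved when 1 library was left out. It was 3925 without shNC 3, including 1374 of the 1377, 688 without shNC 1 and 1013 without shNC 2. It was 513, 468 and 519 without shCUEDC1 1, 2 and 3. A fit with 1 library fewer has less power, so the lower counts do not point at a particular library. Only the fit without shNC 3 gave more. Leaving out 1 library gave between 88 and 363 genes over 2-fold.

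Among the genes that passed the rule for named genes, the largest rise with all 6 libraries was in CALCR, the calcitonin receptor, from 1.20 ± 0.205 to 8.43 ± 0.587 CPM, a log2 change of 2.81 (SE 0.170, edgeR adjusted p = 3.14e-05). PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, rose by 2.19 and TAT, tyrosine aminotransferase, by 2.17. PDZK1, a PDZ scaffold protein and a known oestrogen-induced gene, rose from 30.8 ± 10.9 to 113 ± 3.68 CPM. LYZ (lysozyme) rose by 1.68 and ELOVL2, a fatty acid elongase, by 1.56. SIGLEC6 rose by 2.39, CDH10 by 1.63 and SOCS2 from 1.17 ± 0.515 to 3.34 ± 0.357 CPM, but each of these lost its call when any of 3 single libraries was left out. Their highest adjusted p by edgeR was then 0.0623 for SIGLEC6 (without shNC 1), 0.0535 for CDH10 (without shCUEDC1 1) and 0.0787 for SOCS2 (without shCUEDC1 3). Over the fits that leave out 1 library, the log2 change of SIGLEC6 ranged from 2.04 to 3.16. That of CALCR ranged from 2.71 to 2.95, so their order depends on single libraries.

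Among the largest falls, BPIFB1, a secreted protein of the airway and salivary epithelium, was the most abundant. It fell from 66.8 ± 7.82 to 14.5 ± 1.08 CPM, a log2 change of -2.20 (95% interval -2.43 to -1.98, edgeR adjusted p = 9.27e-06). BPIFA1, of the same family, fell by 2.66 and GLYATL3 by 2.72. IGFBP3, which binds insulin-like growth factors, fell by 1.97, the chemokine CCL2 by 2.01 and SULF2, an extracellular sulfatase, by 2.00. SPRR2A, a cornified envelope protein, fell by 2.01, although reads of its near-identical family members cannot be told apart with certainty. ALDH1A1 fell by 2.10, TWIST1 by 2.31 and KRTDAP by 1.99, at low levels. Their calls were lost without single libraries, with a highest edgeR adjusted p of 0.0933 for ALDH1A1 (without shCUEDC1 1), 0.118 for TWIST1 (without shCUEDC1 1) and 0.118 for KRTDAP (without shNC 1).

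**Figure D2:**
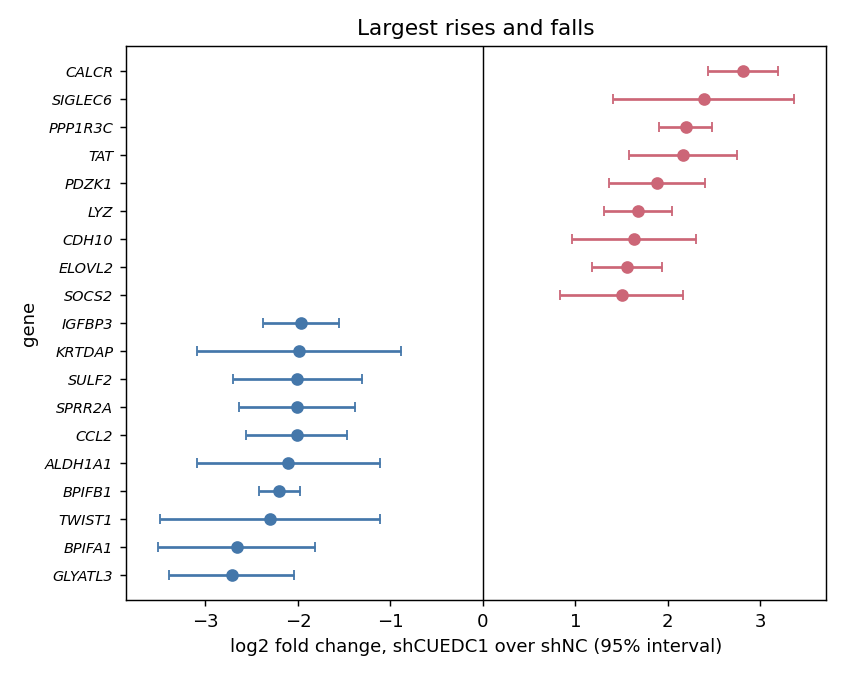
Log2 fold change of shCUEDC1 over shNC with its 95% interval for the largest rises (red) and largest falls (blue) that are reported by the rule for named genes, from 3 libraries per group. CALCR is at 2.81 and GLYATL3 at -2.72. The genes shown were picked as called by the same fit, so no interval could cross 0.

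Voltage-gated calcium channel subunits, the family of CACNG4, changed in both directions. Of 13 tested, 2 rose and 2 fell, and 2 rose and 3 fell when adjusted over the list alone. CACNB4, a beta subunit, rose from 25.6 ± 2.51 to 51.7 ± 1.62 CPM (log2 change 1.01, edgeR adjusted p = 1.12e-04). CACNA1H rose by 0.37, CACNA2D1 fell by 0.69 and CACNG4 fell by 0.53. The list was not called by camera (adjusted p = 0.50). CACNA2D1 had an edgeR adjusted p of 0.179 without shCUEDC1 1, and CACNA1H one of 0.0920 without shCUEDC1 2.

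Genes of PI3K and AKT signalling, the pathway the series reports as enriched, included 7 that rose and 2 that fell among 37 tested, and 7 and 4 when adjusted over the list alone. This list was fixed here rather than taken from the series, and its counts use no fold criterion, so they do not test that enrichment. AKT1, the kinase itself, rose from 208 ± 9.98 to 294 ± 6.18 CPM (log2 change 0.50, edgeR adjusted p = 3.87e-04). IRS1, an insulin receptor substrate, rose by 0.68, and the receptors ERBB2 and ERBB3 by 0.41 and 0.31. PIK3CB, a catalytic subunit, fell by 0.29 and PIK3C2A by 0.27, a pair named after their values were seen. The list was not called by camera (adjusted p = 0.0967, and adjusted p = 0.423 with an estimated correlation), but was called without a low-count filter (0.0370), by DESeq2 (0.0334) and by fry (0.0357), as well as without shNC 3 (0.00914) and without shCUEDC1 3 (0.0443). FOXO targets, which AKT holds in check, had 1 rise (ERBB3) and 1 fall (FBXO32, by 0.41) among 21, the same when adjusted over the list alone. Their median was -0.02, opposite in sign to the camera test, which did not call them (adjusted p = 0.978).

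Glycolysis genes had 2 rises and 4 falls among 26 tested, and 4 and 6 when adjusted over the list alone. ALDOC, aldolase C, fell by 0.60 and GPI, glucose-6-phosphate isomerase, by 0.24, while PFKM, muscle phosphofructokinase, rose by 0.36 and SLC2A10 by 0.34. The list was not called (camera adjusted p = 0.648). Hypoxia response genes had 2 rises and 3 falls among 28 (4 and 5 when adjusted over the list alone, camera adjusted p = 0.978). ERO1A, an endoplasmic reticulum oxidase, rose from 210 ± 8.41 to 337 ± 5.32 CPM, KDM4B rose by 0.44, and EGLN1 and PDK1 fell by 0.29 and 0.44. GPI and SLC2A10 lost their calls without shNC 1 or any 1 shCUEDC1 library, with a highest edgeR adjusted p of 0.0840 and 0.104, and without shCUEDC1 2 the adjusted p of EGLN1 and PDK1 was 0.0547 and 0.123.

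Oestrogen response genes had 11 rises and 3 falls among 38 tested (16 and 5 when adjusted over the list alone, median log2 change 0.15, camera adjusted p = 4.46e-04). The adjusted p was 0.0841 with an estimated correlation. When shNC 3 was left out, with 3925 genes called in all, 22 of these genes rose and 9 fell. TSKU rose from 127 ± 12.6 to 210 ± 11.5 CPM, TFF1, a secreted trefoil peptide, by 1.01, and PDZK1 and ELOVL2 as above. Luminal identity genes had 7 rises and 2 falls among 28 (10 and 2 when adjusted over the list alone, median 0.18, camera adjusted p = 2.94e-05, and adjusted p = 0.0825 with an estimated correlation). AGR3 rose from 55.7 ± 1.21 to 90.5 ± 4.45 CPM, AGR2 by 0.54 and the mucin MUC1 by 0.44, while the transcription factor TFAP2B fell by 1.47.

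Basal and mesenchymal markers had 1 rise and 5 falls among 20 tested (1 and 8 when adjusted over the list alone, median -0.41, camera adjusted p = 6.49e-04, and adjusted p = 0.146 with an estimated correlation). SPARC fell from 6.93 ± 1.41 to 2.51 ± 0.222 CPM, KRT6B by 0.68 and the integrin ITGA6 by 0.41, while fibronectin, FN1, rose by 0.87. KRT6B has near-identical copies and is uncertain for that reason. The median of this list in shNC 3 lay 0.35 below that of shNC 1 and 2 on the log2 scale (-0.35), against -0.44, -0.54 and -0.36 in the shCUEDC1 libraries. Stromal and immune markers had 1 rise, COL1A1 by 0.61, and 0 falls among 12, the same when adjusted over the list alone (camera adjusted p = 0.293, and 0.0462 by limma-trend on FPKM, where the list was called). The leukocyte marker PTPRC was at 0.713 CPM in shNC and 0.548 CPM in shCUEDC1, and COL1A1 had an edgeR adjusted p of 0.0599 without shCUEDC1 3.

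Interferon-stimulated genes had 15 rises and 0 falls among 34 tested, with 19 not called (22 and 0 when adjusted over the list alone, median log2 change 0.20, camera adjusted p = 3.44e-10). The adjusted p was 0.248 with an estimated correlation. DDX58, the RNA sensor RIG-I, rose from 408 ± 26.5 to 539 ± 9.47 CPM, and RSAD2, DDX60 and PARP9 by 0.33, 0.37 and 0.28. The median of the list in shNC 3 was -0.15 relative to shNC 1 and 2.

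TGF beta targets had 0 rises and 7 falls among 24 tested (1 and 11 when adjusted over the list alone, median -0.22, camera adjusted p = 1.84e-04, and adjusted p = 0.0825 with an estimated correlation). Without shNC 3, where 3925 genes were called in all, 3 of these targets rose and 12 fell. ID1, an inhibitor of differentiation, fell from 96.6 ± 7.74 to 70.8 ± 1.79 CPM, the inhibitory SMAD6 by 0.74, LTBP1 by 0.39 and PMEPA1 by 0.38. Targets of p53, whose gene is mutated in T47D, had 0 rises and 7 falls among 23 (1 and 10 when adjusted over the list alone, median -0.21, camera adjusted p = 9.02e-05, and adjusted p = 0.0825 with an estimated correlation). The counts of p53 targets were 2 rises and 11 falls without shNC 3. ZMAT3 fell from 104 ± 5.23 to 71.0 ± 0.564 CPM, RRM2B by 0.49, TP53INP1 by 0.32 and TP53I3 by 0.26. TP53INP1 and TP53I3 had edgeR adjusted p of 0.0784 and 0.0517 without shCUEDC1 2.

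Cholesterol synthesis genes had 0 rises and 7 falls among 24 tested (0 and 11 when adjusted over the list alone, median -0.20, camera adjusted p = 1.22e-05, and adjusted p = 0.373 with an estimated correlation). The methylsterol oxidase MSMO1 fell from 123 ± 16.3 to 78.1 ± 0.774 CPM, DHCR7 by 0.35 and FDFT1 by 0.21. In shNC 3 the list's median was 0.14 above shNC 1 and 2. Fatty acid synthesis genes had 2 rises and 6 falls among 20 (2 and 7 when adjusted over the list alone, camera adjusted p = 0.0967), with falls of 0.97 for THRSP, 0.61 for LPIN1, 0.51 for FADS2 and 0.42 for FADS1. Without shNC 2 this list was called (adjusted p = 0.00658), but without shNC 3 the adjusted p was 0.723. Its median was -0.05 with all libraries and -0.02 without shNC 3, which lay at 0.17 relative to shNC 1 and 2. FDFT1 and THRSP lost their calls without shNC 1 or any 1 shCUEDC1 library, and the highest edgeR adjusted p was 0.115 and 0.0802. It was 0.0550 for DHCR7 and 0.0612 for FADS1 without shCUEDC1 2, 0.0524 for LPIN1 without shCUEDC1 3 and 0.0839 for FADS2 without shCUEDC1 1.

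Mitotic genes of G2 and M phase had 5 rises and 0 falls among 30 tested (6 and 0 when adjusted over the list alone, median 0.10, camera adjusted p = 4.65e-04, and adjusted p = 0.456 with an estimated correlation). TOP2A, topoisomerase II alpha, rose from 385 ± 8.52 to 487 ± 29.4 CPM, AURKB by 0.36, DLGAP5 by 0.24 and BIRC5 (survivin) by 0.22. AURKB, DLGAP5 and BIRC5 had edgeR adjusted p of 0.135, 0.128 and 0.143 without shCUEDC1 1. Genes of G1 and S phase had 2 rises and 0 falls among 30, the same when adjusted over the list alone (camera adjusted p = 0.118), with MCM6 up by 0.48 and MCM2 by 0.22 (edgeR adjusted p of MCM2 0.162 without shCUEDC1 2). That list was called without shNC 1 (adjusted p = 0.00542) and without shCUEDC1 3 (0.0486), but had an adjusted p of 0.795 without shNC 3. Its median was 0.05 with all libraries and -0.001 without shNC 3, and shNC 3 lay at -0.19 relative to shNC 1 and 2.

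The remaining lists were not called by camera with all 6 libraries. ATF4 and unfolded protein response genes had 0 rises and 3 falls among 30 (0 and 4 when adjusted over the list alone, adjusted p = 0.0967): PSAT1 fell by 0.52, ALDH1L2 by 0.35 and DNAJB9 by 0.26. That list was called without shNC 1 (0.0360), without shNC 3 (0.0274) and without shCUEDC1 3 (0.0443). Immediate early genes had 1 rise (DUSP5, 0.28) and 2 falls (SPRED1 and CCN1, by 0.51 and 0.42) among 27, or 2 and 5 when adjusted over the list alone (adjusted p = 0.151), and were called without shNC 1 (0.0270) but had an adjusted p of 0.723 without shNC 3. Their median was -0.17 with all libraries and -0.04 without shNC 3, which lay at 0.24 relative to shNC 1 and 2. Nuclear genes of the respiratory chain had 1 rise (UQCRQ, 0.40) and 1 fall (CYC1, by 0.21) among 35, the same over the list alone (adjusted p = 0.359), and were called without shNC 3 (0.0486). Replication-dependent histones had 1 rise, H2BC4 by 0.28, and 0 falls among 14 (adjusted p = 0.138, and 0.0346 by limma-trend on FPKM), and ribosomal proteins 1 rise, RPL10 by 0.26, and 0 falls among 38 (adjusted p = 0.953), the same over each list alone. H2BC4 has near-identical copies. Without shCUEDC1 2 the edgeR adjusted p was 0.0699 for PSAT1, 0.135 for DNAJB9, 0.0993 for CCN1, 0.107 for SPRED1, 0.143 for DUSP5 and 0.138 for CYC1, and without shCUEDC1 1 it was 0.0724 for ALDH1L2 and 0.0801 for H2BC4. For ribosomal proteins the median (0.001) and the camera test differed in sign.

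Calls of the 8 lists differed between set tests. With an estimated correlation 0 of 21 lists were called, with a lowest adjusted p of 0.0825. Other splits of the same 6 libraries, which each mix both groups, gave up to 10 called lists. Fry, which tests whether a list's genes move one way and does not compare them with other genes, called 6 of the 8. It gave adjusted p of 0.00361 for oestrogen response, 0.00265 for luminal identity, 0.0357 for basal and mesenchymal markers, 0.0300 for interferon response, 0.00265 for TGF beta targets and 0.00361 for p53 targets. It did not call cell cycle G2 M or cholesterol synthesis (both 0.0544).

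**Figure D3:**
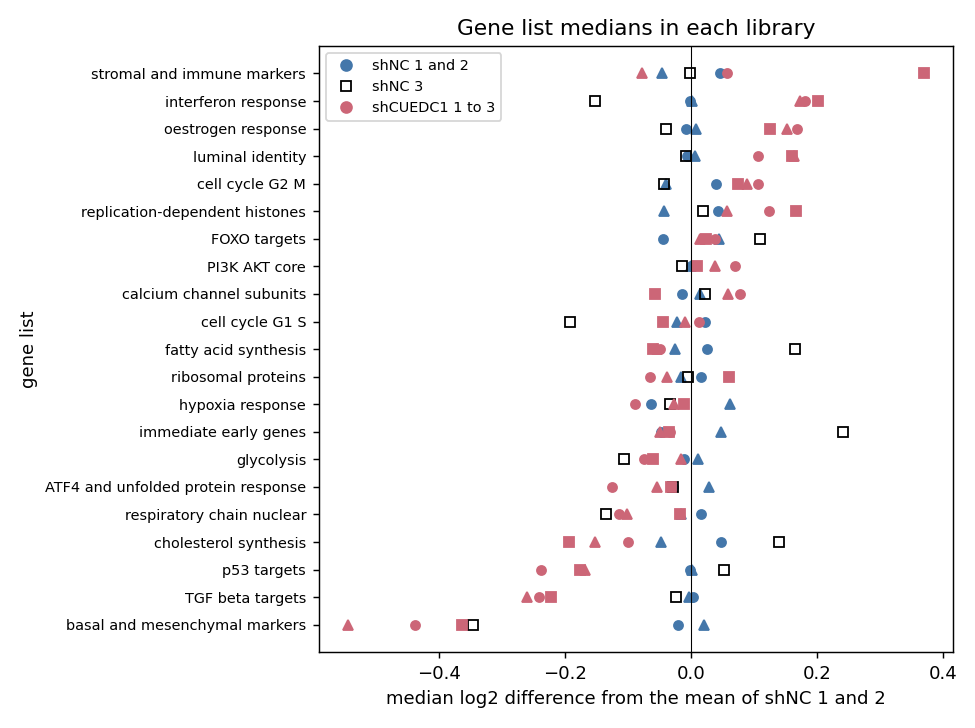
Median log2 difference of each gene list from the mean of shNC 1 and 2 (x axis), with blue points for shNC 1 and 2, an open black square for shNC 3 and red points for the 3 shCUEDC1 libraries (circle, triangle and square for replicates 1, 2 and 3). The interferon list lies at 0.18, 0.17 and 0.20 in shCUEDC1 and at -0.15 in shNC 3.

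Called genes were also counted by position, and the stretches given here were picked out after the values were seen. On chromosome 14, 58 genes rose and 4 fell among 388 with a mean of at least 5 CPM, with a median log2 difference of 0.11. The counts were 64 and 17 among 598 on chromosome 12 (median 0.04) and 47 and 16 among 373 on chromosome X (0.05). They were 28 and 7 among 786 on chromosome 19 (0.04). Over all genes tested, with no minimum of 5 CPM, 717 rose and 660 fell, which is not a matched baseline for these counts. On chromosome 14 from 21521081 to 24379604 (GRCh38), between SALL2 and NFATC4, 43 of 44 genes with a mean of at least 5 CPM were higher in shCUEDC1. Their median was 0.25. Relative to shNC 1 and 2, the median of this stretch was 0.14 in shNC 3 and 0.29 to 0.30 in the shCUEDC1 libraries. This stretch holds PSME1, PSME2 and IRF9, of which IRF9 is an interferon list member that rose by 0.23. On chromosome X from 153972327 to 155026940, between TMEM187 and F8, all 20 genes were higher, with a median of 0.26, RPL10 among them. The median there was -0.09 in shNC 3 relative to shNC 1 and 2. AKT1 lies on chromosome 14 from 104769349 to 104795751, and its 14 nearest neighbours had a median of 0.04.

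**Figure D4:**
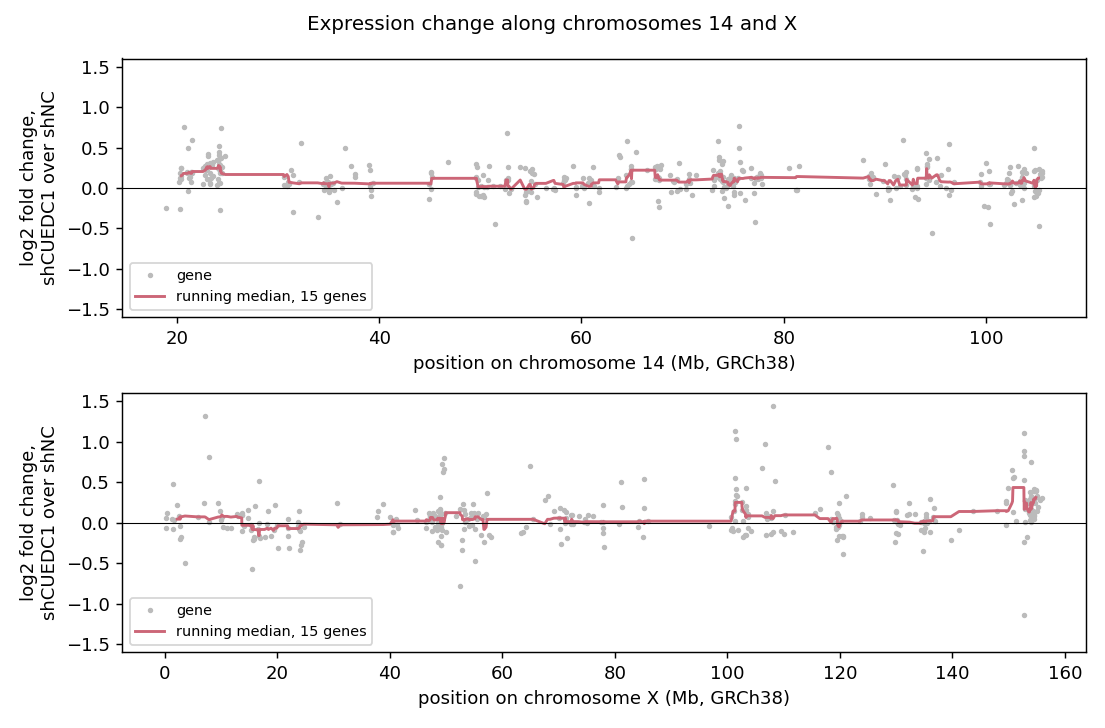
Log2 fold change of shCUEDC1 over shNC against position on chromosomes 14 and X (Mb, GRCh38), with a grey point per gene and a red line for the running median of 15 neighbouring genes. The line reaches 0.28 on chromosome 14 between SALL2 and NFATC4 and 0.44 near the end of chromosome X.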

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

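Apart from the offsets for GC content and transcript length, which were chosen after seeing the data, the alternatives were fixed before the data were examined. CUEDC1 and CACNG4 kept their direction and their call under each of them. Leaving out 1 library at a time gave 468 to 3925 changed genes against 1377, and 88 to 363 changed more than 2-fold against 162. The highest counts came without shNC 3. Over genes with a mean of at least 10 CPM, its SD of log2 deviation from the group mean was 0.167. It was 0.073 to 0.108 in the other libraries, and a link to the counts was not tested. Limma-trend on FPKM gave 63 genes over 2-fold, and the cause was not tested. With GC and length offsets 1882 genes were changed. With the replicate number as a block 1117 genes were changed and 144 more than 2-fold. Deviations of same-numbered libraries correlated at -0.01, -0.05 and -0.02, so no large shift shared by same-numbered libraries was seen. The correlations cannot tell whether those libraries were handled in pairs. With an estimated correlation 0 lists were called against 8. SLC2A1, not called in any fit, was 0.00371 without a filter, 0.00142 by DESeq2, and -0.0390 to 0.0234 over the fits that leave out 1 library. LDHA, also not called, was -0.0915 without shNC 3 and at most 0.165 without another library. Of 85 called genes picked by the naming rule, 51 kept the call in every fit that leaves out 1 library and 34 lost it in at least 1. Of these genes 0 changed sign, but the groups of all 1377 called genes did not overlap. Leaving out 1 library could therefore hardly turn a sign, and this count says nothing about stability. Limma-trend on FPKM ended 8 of these calls (TWIST1, CACNA1H, CACNA2D1, GPI, BIRC5, AURKB, MCM2 and PDK1), limma-voom 2 (TWIST1 and CACNA2D1), the offsets 1 (CACNA2D1) and the replicate block 6 (SIGLEC6, KRTDAP, CACNA2D1, MCM2, CYC1 and DUSP5).

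Lists that were not called turned direction in some fits. Values given without a range are adjusted p of fits that turned, and ranges are over all fits that leave out 1 library, including those that kept the direction. Calcium channel subunits had 0.998 without a filter, 0.997 by DESeq2 and 0.809 by limma-trend on FPKM. Hypoxia had 0.973 without a filter, 0.974 by DESeq2, 0.994 by fry, and a range of 0.403 to 0.984 (turned without shNC 2 and without shCUEDC1 1). Ribosomal proteins had 0.973 without a filter, and a range of 0.155 to 0.874 (turned without shNC 1, without shCUEDC1 1 and without shCUEDC1 2). FOXO targets had a range of 0.677 to 0.982 (turned without shNC 1 and without shCUEDC1 3), and glycolysis one of 0.0623 to 0.837 (turned only without shNC 2). The cause was not tested. TWIST1 and KRTDAP had no value under the strict filter, and KRTDAP no adjusted p by DESeq2. Pathway enrichment and the alternatives for an FPKM-only table were not run.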

Other observations

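The tests of mixing and of GC content as the whole cause for shNC 3, of the held-out neighbouring genes, of the chance splits of the gene counts, and of leaving out shNC 3 were chosen only after the result was seen.

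Of 8 tested MTRNR2L genes, which share sequence with the mitochondrial 16S ribosomal RNA, 7 were called lower in shCUEDC1, 0 higher and 1 was not called. They were picked out after their values were seen, and no set test was made. MTRNR2L2 went from 3407 ± 174 to 2709 ± 143 CPM (log2 change -0.33, edgeR adjusted p = 0.00607) and MTRNR2L8 from 1485 ± 75.0 to 1105 ± 98.3 CPM (-0.43, adjusted p = 0.00437). MTRNR2L1 changed by -0.49 (adjusted p = 9.72e-04) and MTRNR2L9 by -0.72 (0.00437). These copies cannot be told apart from each other or from mitochondrial transcripts by their reads, so the family is uncertain.

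The library shNC 3 stood apart from shNC 1 and 2 in genes also picked out after their values were seen. ANXA1 was at 16.7 CPM against 50.8 and 48.1, FLNA at 40.3 against 86.1 and 92.5, and FHL2 at 44.1 against 104 and 116. PIP was higher, at 2004 against 850 and 954 CPM. Over 10105 genes the difference of shNC 3 from shNC 1 and 2 followed GC content with a Spearman correlation of -0.47 across genes, which are not independent replicates. A fit on GC content and transcript length took 19.0% of its variance, which argues against such a bias as the whole cause. Mixing with knockdown RNA would shift rising and falling genes by the same share. Yet among genes over 2-fold without shNC 3, the median share was 0.228 for 111 rising and 0.608 for 212 falling genes. The difference was 0.380 (95% bootstrap interval 0.269 to 0.463). The bootstrap resampled genes, which are not independent replicates, so its interval does not cover the spread between libraries. Part of the shift may follow GC content, and a difference in culture or handling stays open and was not tested.

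Blocks of neighbouring genes were higher in shCUEDC1. Only raised blocks were searched for: the lowest running median of 15 genes was -0.241 and was not set against permutations. The highest running median reached 0.44, above the largest value of 0.312 in 1000 permutations of the gene order, whose 95th percentile was 0.241. The blocks above that percentile were chromosome 14 from SALL2 to NFATC4 and chromosome X from RPL36A to ARMCX5-GPRASP2, from MTM1 to MAGEA1 and from TMEM187 to F8. From MTM1 to MAGEA1, 13 of 15 genes were higher, and MAGEA6 changed by -1.145 (edgeR adjusted p = 6.40e-04), which a gain of copies alone would not give. Reads of near-identical MAGEA and CSAG family members cannot be told apart with certainty, so the fall of MAGEA6 and this count are uncertain. The medians of these 4 blocks were 0.231 to 0.376 without shNC 3 and 0.227 to 0.302 with GC and length offsets, against 0.245 to 0.326. Over all 118 genes of the 9 blocks with a running median of at least 0.2, of which 5 did not pass the percentile, the median was 0.28 and 0.24 against 0.25, which argues against that library or such a bias as the cause. When blocks were located on every other gene, 93.2% of the 44 genes held out (41 genes) were higher in shCUEDC1, against 50.5% of all remaining genes searched. A copy-number difference between the lines would give this, but so would any shift shared by neighbouring genes. Those higher were 20 of 20 on chromosome 14 from ABHD4 to LTB4R, 15 of 16 on chromosome X from CSAG1 to PLXNA3, and 6 of 8 on chromosome 19 from ZNF230 to APOE. The stretches from RPL36A to ARMCX5-GPRASP2, from LAGE3 to F8 and from MTM1 to CSAG2, which holds the highest running median, were not located again on those genes. These stretches were therefore not tested in this way. Relative to shNC 1 and 2, the SALL2 to NFATC4 median was 0.143 in shNC 3 and 0.286 to 0.303 in shCUEDC1. From RPL36A to ARMCX5-GPRASP2 it was 0.183 against 0.314 to 0.408. From MTM1 to MAGEA1 it was 0.052 against 0.317 to 0.421, and from TMEM187 to F8 -0.092 against 0.212 to 0.232. A copy-number difference between the lines would not by itself give the raised medians in shNC 3. A shared regulation of neighbouring genes stays open, since no DNA was analysed here, and so does the knockdown itself.

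Interferon-stimulated genes were higher in shCUEDC1 by a median of 0.20. The median was 0.19 without shNC 3, where 21 rose and 1 fell, and 0.21 with GC and length offsets, where 18 rose and 0 fell, so neither that library nor such a bias accounts for the whole of it. A response to the hairpin or virus that differs between the lines may contribute, and it cannot be separated from the loss of CUEDC1 with 1 knockdown condition.

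The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1377 changed genes and 162 over 2-fold by edgeR, and was the only 1 of the 10 to give as many. The highest of the others was 0 for both counts, with 75 to 936 genes at an unadjusted p under 0.05. Each other split mixes libraries of both groups, so a real group difference would widen its spread and lower its counts. The 0 is therefore not a measure of chance. For the list tests, 4 of the 10 splits gave at least as many called lists as the real 8, and the highest of the others was 10. Part of a group difference can stay in a mixed split, so this count does not measure chance alone either.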
